A study of Arabidopsis thaliana with 27 samples.

How the data were processed

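The TPM values were made by the authors and used as deposited: per the file headers the table holds 1 TPM column per library for 33039 genes in 27 libraries, with a mean column for each of 9 groups, a length column and a functional annotation. The aligner, the quantifier and the genome build behind these values are not given in the sources used here, so no coordinates are printed. Values carry 2 decimals. The authors' mean columns differed from the means of 3 libraries by at most 3.3e-05 TPM, within a tolerance of 0.0001. Of the gene IDs, 32547 matched locus tags of the TAIR10.1 RefSeq annotation, which was used for names alone; 207 others are assembled loci with MSTRG names. 1 table line had no values and is not analysed here. For the insertion line at 16 °C the replicate numbers in titles, descriptions and columns differ, so 2 columns are tied to that group but not to a replicate label. Replicate numbers given below for this group are those of the columns and name no sample.

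Values were transformed to log2(TPM + 1), and 21396 genes with at least 1 TPM in at least 3 libraries were tested. A linear model with a mean for each of the 9 groups was fitted with limma (version 3.58.1, R 4.3.3), with variances moderated along a trend in mean expression, 18 residual and 3.17 prior degrees of freedom. 18 comparisons were drawn from this fit, each two-sided with Benjamini-Hochberg adjustment over the tested genes, and a gene was called at adjusted p < 0.05. Every adjusted p of a gene in the text is from this limma test. The comparisons, the gene lists, the test and the rule for named genes were fixed before the data were examined. On simulated data for the S364P line against wild type at 16 °C over 21396 genes, 55% of changes of 0.5 log2 and 89% of changes of 1 log2 were called, with 7 false calls among 151.

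The 19 gene lists held 293 genes: morning clock, evening clock, known evening complex targets, PIF and auxin growth, brassinosteroid and gibberellin enzymes, flowering promoters, flowering repressors, heat shock, cold response, photosynthesis, flavonoid and anthocyanin, salicylic acid defence, jasmonate response, abscisic acid and drought, dark and sugar starvation, rapid touch and wound, root, flower organ and seed. The last pair, flower organ and seed markers, had too few tested members for a result, and 46 list genes were below the filter. The other 17 lists were tested with camera in limma, with a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists of a comparison. The test was repeated with an estimated correlation. Of 159 list calls, 79 held with it and 80 ended. A list call printed without that outcome is given for the preset correlation alone. List counts are given over all tested genes and adjusted over the list alone. The lists overlap, so results of lists with shared genes are not separate evidence. Every evening complex target is also in another list: PRR7, PRR9 and LNK1 in morning clock, GI, LUX and BOA in evening clock, PIF4 and PIF5 in growth.

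Genes were named by rule: 19 core genes in each comparison, at most 4 called members per list with the largest difference, and the 5 largest rises and falls among called genes with a mean of at least 5 TPM and no overlap between libraries of the groups compared. By chance 10% of genes show no overlap between 3 and 3 libraries. For 1064 biological process terms of 10 to 500 members among 20262 annotated genes, called genes in each direction were tested with a one-sided Fisher's exact test, adjusted over the terms of a comparison and direction. Terms were tested on the calls from TPM alone, without another scaling.

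The similarity of both alleles' effects was taken across genes as Pearson's r, as a covariance and as a slope corrected for the noise shared through the wild-type libraries, and compared with 20 simulated data sets without effects. Alternatives were a minimum difference of 1 log2, pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, removal of 285 organelle-encoded genes, a fit of the groups compared alone, the replicate number as a block, and leaving out each library. The root score as a covariate, the mean of the root markers centred within groups, was added after seeing the data. So was a test of the DNA integration term among genes at 1 TPM or more in at least 3 wild-type or insertion-line libraries. Other computations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.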

Results

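Messenger RNA of whole Arabidopsis thaliana seedlings was profiled in 27 libraries that form 9 groups of 3. The 3 genotypes were Columbia wild type, the S364P line, whose EARLY FLOWERING 3 (ELF3) protein carries a serine to proline change, and a line with a T-DNA insertion in ELF3. Each genotype was sampled at 16, 22 and 29 °C. ELF3 is the scaffold of the evening complex, a repressor of transcription that it forms with ELF4 and LUX, and it links the circadian clock and ambient temperature to growth. The deposited text asks how the changed residue, treated there as a phosphorylation site, bears on flowering time and on hypocotyl length. The protocol in the labels lists Zeitgeber times of 8, 16 and 24 h in parallel with the 3 temperatures. Read literally, each temperature had its own time of day. A difference between temperatures can then also be a difference between times of day, while genotypes compared at 1 temperature share both.

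Expression values were in TPM, which scales every library to the same total and keeps no sequencing depth. The depth of each library is therefore unknown and no counting interval is given. Each library had 23430 to 23854 genes above 0 and 19164 to 20084 genes at 1 TPM or more. Replicates of a group correlated across genes at r = 0.973 to 0.987 on the log2(TPM + 1) scale in 27 pairs, and libraries of different groups at 0.859 to 0.983 in 324 pairs. Nothing in the labels says that replicates came from separate plantings. The p-values measure only the spread between these samples, which may be technical. Root marker transcripts differed between libraries: the mean log2(TPM + 1) of 17 root markers was 2.82 in replicate 1 of the S364P line at 29 °C against 1.95 and 1.87 in replicates 2 and 3. Other groups also varied, with 3.37, 2.69 and 2.97 in wild type at 22 °C. The share of root tissue was not measured. Below, TPM values are mean ± SD with n = 3, and log2 differences are on the log2(TPM + 1) scale ± SE.

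ELF3 (AT2G25930) transcripts were present in all libraries of the insertion line, at 32.3 ± 1.60 TPM at 16 °C, 35.4 ± 3.83 at 22 °C and 39.7 ± 1.98 at 29 °C. Wild type had 27.1 ± 1.97, 20.4 ± 2.54 and 40.3 ± 1.38 TPM. The insertion line was higher than wild type at 22 °C by 0.76 ± 0.078 (adjusted p = 5.07e-08), and differed by -0.02 at 29 °C (adjusted p = 0.869). At 16 °C the difference was 0.25 (adjusted p = 0.0214); it no longer passed without wild-type replicate 1 (0.19, adjusted p = 0.121) or without insertion-line replicate 2 (0.22, adjusted p = 0.0758) or 3 (0.23, adjusted p = 0.0635), nor in a fit of these 6 libraries alone (adjusted p = 0.0531). The position of the insertion is not given in the sources used here, and a gene-level TPM sums reads from either side of it, so these levels check nothing about the loss of ELF3 function. In the S364P line ELF3 was at 30.7 ± 1.60 TPM at 16 °C, where the difference from wild type of 0.17 did not pass (adjusted p = 0.484). It rose to 46.9 ± 0.813 TPM at 22 °C and 69.8 ± 2.23 at 29 °C, above wild type by 1.17 and 0.78 (adjusted p = 1.35e-10 and 5.15e-08).

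**Figure D1:**
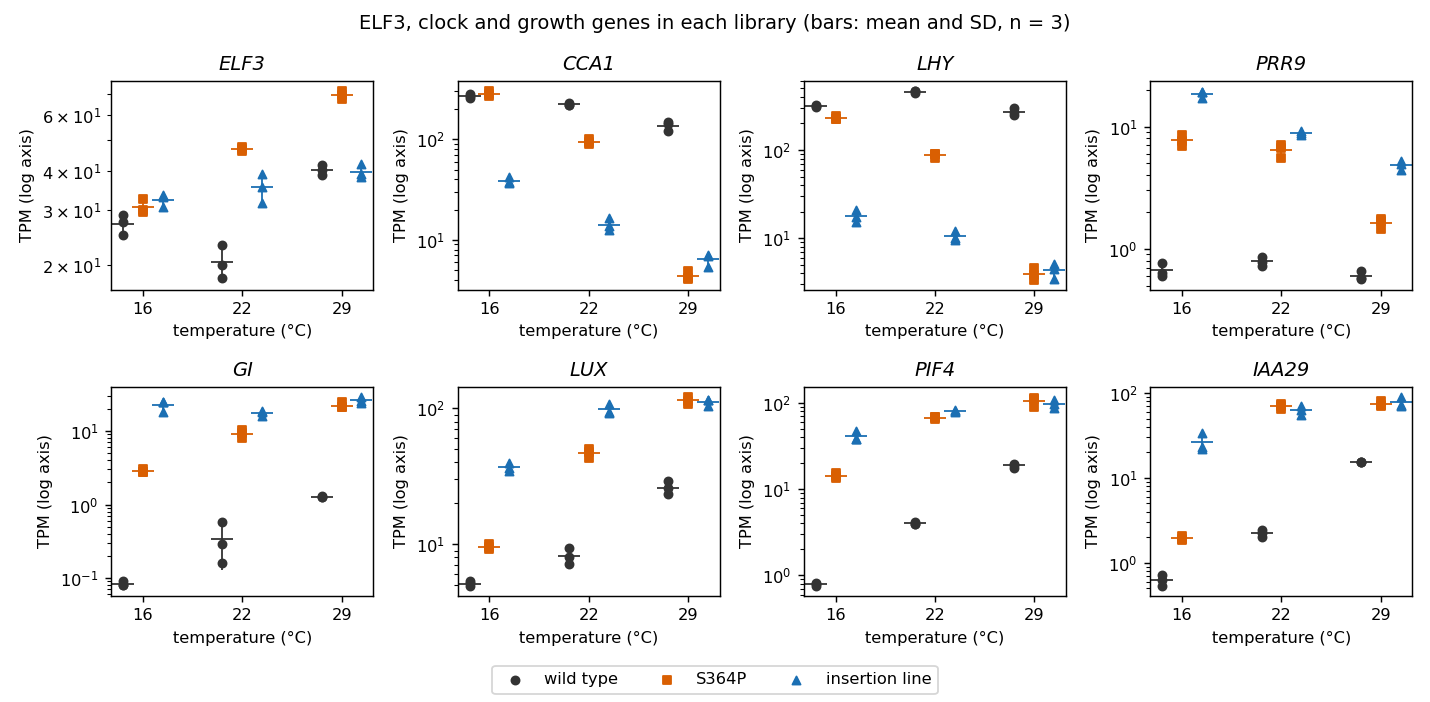
TPM of ELF3, clock genes and growth genes in each library (log axis) against temperature in °C, with points for libraries and bars for the mean and SD of 3 libraries per genotype. CCA1 in the S364P line was at 285 TPM at 16 °C and 4.38 TPM at 29 °C, and the insertion line was at 38.9 and 6.43 TPM.

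The first comparison asks what the ELF3 insertion changed in seedlings at 16 °C. Direct targets of the evening complex were higher in the insertion line. PIF4 (AT2G43010), a transcription factor that drives warmth-induced elongation, was at 41.1 ± 5.72 TPM against 0.787 ± 0.0321 in wild type. The clock repressor PRR7 (AT5G02810) was at 51.0 ± 7.77 against 0.967 ± 0.188. GIGANTEA (GI, AT1G22770), an evening clock gene, was at 22.7 ± 4.03 TPM against 0.0833 ± 0.00577. The morning transcription factors CCA1 (AT2G46830) and LHY (AT1G01060) were lower, at 38.9 ± 2.98 against 270.1 ± 11.8 TPM and 17.84 ± 3.01 against 313 ± 8.28 TPM. The auxin response gene IAA29 was at 26.2 ± 6.54 against 0.623 ± 0.0902 TPM. GBSS1, which makes amylose in leaf starch, was at 3.38 ± 0.946 against 126 ± 11.1 TPM.

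All 8 known evening complex targets tested rose at 16 °C in the insertion line (8 adjusted over the list alone; median log2 difference 3.14, camera adjusted p = 7.14e-21), led by PRR7 (4.72 ± 0.121), PIF4 (4.55 ± 0.088) and GI (4.44 ± 0.12). Of 33 PIF and auxin growth genes, 31 rose and none fell (32 and 0 adjusted over the list alone; median 1.27, adjusted p = 6.08e-27), among them IAA29 by 4.04 and IAA19 by 3.14. Of 11 evening clock genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 1.66, adjusted p = 9.41e-13). Of 16 flavonoid and anthocyanin genes, 15 fell (16 adjusted over the list alone; median -2.15, adjusted p = 1.75e-25), with LDOX at -2.85 and FLS1 at -2.57. These 4 calls held with an estimated correlation between genes. The 13 morning clock genes went both ways, 5 up and 6 down (6 and 7 adjusted over the list alone; median -0.23, mean 0.12, adjusted p = 0.931). PRR7 and PRR9 rose while CCA1 (-2.77 ± 0.098) and LHY (-4.07 ± 0.112) fell. Of 13 dark and sugar starvation genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.87, adjusted p = 1.22e-07), including DIN1 (3.58) and DIN6 (2.89). Of 10 rapid touch and wound genes, 8 rose (9 adjusted over the list alone; median 0.90, adjusted p = 3.82e-05). With an estimated correlation these last calls ended, at adjusted p = 0.055 and adjusted p = 0.111. In all, 3318 genes were higher and 2283 lower of 21396 tested, and 717 also differed by at least 1 log2, 357 of them higher. The share of higher calls, 59.2%, was 49.3% with median-of-ratios scaling and 50% with quantile normalization.

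At 22 and 29 °C the same targets stood apart from wild type. LUX (AT3G46640), the DNA-binding member of the evening complex and itself one of its targets, was at 98.3 ± 8.71 against 8.19 ± 1.09 TPM at 22 °C and at 111 ± 6.39 against 26.2 ± 2.92 TPM at 29 °C. LHY was at 10.6 ± 1.32 against 461 ± 12.4 TPM at 22 °C and 4.32 ± 0.807 against 272 ± 24.4 TPM at 29 °C. XTR7, a cell wall enzyme of shade and warmth growth, reached 1715 ± 202 against 56.2 ± 14.2 TPM at 29 °C. The light-harvesting gene LHCB2.1 fell to 439 ± 24.9 against 1874 ± 140 TPM at 22 °C and to 175 ± 6.61 against 888 ± 54.8 TPM at 29 °C.

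Evening complex targets were up in 8 of 8 members at both temperatures (8 and 8 adjusted over the list alone; medians 3.06 and 1.96, adjusted p = 1.43e-12 and 2.3e-11). PIF and auxin growth genes rose in 28 and 31 of 33 members and fell in 0 and 1 (adjusted over the list alone, 28 and 31 rose and 1 and 1 fell; medians 1.74 and 1.16, adjusted p = 1.6e-20 and 1.68e-15). ST2A was up by 5.05 and 3.63. Photosynthesis genes fell in 11 and 19 of 24 members and rose in 5 and 3 (adjusted over the list alone, 11 and 20 fell and 5 and 4 rose; medians -0.14 and -0.71, adjusted p = 2.83e-04 and 3.11e-15). With an estimated correlation the call at 22 °C ended (adjusted p = 0.341) and that at 29 °C held (adjusted p = 0.0388). Cold response genes rose in 10 and 11 of 17 members with none lower (10 and 11 adjusted over the list alone; medians 0.50 and 0.78, adjusted p = 2.99e-04 and 1.8e-05), led by COR413IM1 (5.83 and 4.53) and COR27 (4.30 and 2.62). Abscisic acid and drought genes rose in 8 of 10 members at 29 °C (9 adjusted over the list alone; median 0.87, adjusted p = 4.12e-04), among them RD20 (1.29 ± 0.164) and the phosphatase gene ABI1 (1.145 ± 0.074). At 22 °C 4 of 10 rose and 1 fell (4 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.154). The counts were 5259 higher and 3928 lower at 22 °C, and 5302 higher and 2887 lower at 29 °C, with 1338 (613 higher) and 939 that differed by at least 1 log2. At 29 °C 64.7% of called genes were higher. This share was 47.0% with median-of-ratios scaling and 52.7% with quantile normalization. At 29 °C the photosynthesis term led the falling terms, with 101 of 163 genes lower against 22.4 expected (one-sided Fisher's exact test, adjusted p = 1.91e-43). Vesicle-mediated transport led the rising terms, with 151 of 268 genes against 67.8 expected (adjusted p = 1.8e-24). The terms were not tested with the other scalings, which lowered the share of higher calls.

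The S364P line at 16 °C differed from wild type in few genes, and evening complex targets were among those with the clearest changes. PIF4 was at 14.3 ± 1.02 TPM against 0.787 ± 0.0321 in wild type, PRR7 at 16.8 ± 0.904 against 0.967 ± 0.188. PRR9 (AT2G46790) was at 7.71 ± 0.812 against 0.667 ± 0.0907, and LNK1, a clock coactivator gene, at 20.34 ± 0.803 against 2.79 ± 0.615 TPM. CCA1 was at 285 ± 19.6 against 270.1 ± 11.8 TPM, and LHY at 230.3 ± 10.1 against 313 ± 8.28 TPM, a difference of -0.44 that did not pass (adjusted p = 0.0504). The assembled locus MSTRG.15205 was listed at 0 TPM in all wild-type and insertion-line libraries and was at 134 ± 7.34 TPM in the S364P line. QQS (AT3G30720), an orphan gene linked to starch and protein allocation, was at 148 ± 5.50 against 1.26 ± 0.714 TPM in wild type and 18.17 ± 8.80 in the insertion line.

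Of the 8 evening complex targets, 7 rose at 16 °C in the S364P line (8 adjusted over the list alone; median 2.11, adjusted p = 9.27e-59), with PRR7 up by 3.18 ± 0.121, PIF4 by 3.09 ± 0.088, LNK1 by 2.504 ± 0.102 and PRR9 by 2.38 ± 0.089. Flavonoid and anthocyanin genes fell in 11 of 16 members (15 adjusted over the list alone; median -0.76, adjusted p = 5.86e-33), with FLS1 at -0.98 ± 0.136. This call held with an estimated correlation. Photosynthesis genes rose in 10 of 24 members (13 up and 1 down adjusted over the list alone; median 0.27, adjusted p = 4.02e-18; adjusted p = 0.0273 with an estimated correlation), among them the antenna genes LHCB3 (0.98 ± 0.098) and LHCA4 (0.94 ± 0.097). Of 33 PIF and auxin growth genes 7 rose (11 adjusted over the list alone; median 0.23, adjusted p = 2.64e-16). Of 13 morning clock genes 5 rose with none lower (6 and 3 adjusted over the list alone; median 0.11, adjusted p = 1.74e-11). These included PRR7, LNK1 and PRR9, already counted as evening complex targets. Cold response genes fell in 2 of 17 members (4 adjusted over the list alone), of which COR15A fell by 1.63 ± 0.23 (list median -0.11, adjusted p = 0.00161, and adjusted p = 0.0551 with an estimated correlation). No member of the heat shock, salicylic acid defence, flowering promoter or abscisic acid lists passed the test. In all, 152 genes were higher and 158 lower, a near balance that leaned to 161 higher and 108 lower with a pseudocount of 0.1 and to 133 and 223 with a pseudocount of 5. Of these, 62 differed by at least 1 log2, 50 of them higher. The count fell to 191 without wild-type replicate 2, 197 without S364P replicate 3 and 204 without S364P replicate 1. Higher genes included 17 members of the DNA integration term, but 15 of these passed the expression filter only through S364P libraries. Among genes that passed it in the other genotypes, a test chosen after seeing the data, 2 of 21 members were higher and the term did not pass (adjusted p = 0.227). Of other biological process terms, light harvesting in photosystem I was up in 11 of 25 genes against 0.18 expected (adjusted p = 3.19e-15), and flavonoid biosynthesis was down in 9 of 22 against 0.16 (adjusted p = 2.26e-11).

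At 22 and 29 °C the S364P line moved far from wild type. CCA1 was at 94.5 ± 6.34 against 224 ± 3.80 TPM at 22 °C and at 4.38 ± 0.403 against 137 ± 13.6 TPM at 29 °C, and LHY at 86.9 ± 5.16 against 461 ± 12.4 and 3.93 ± 0.579 against 272 ± 24.4 TPM. PIF4 rose to 67.0 ± 1.99 and 105 ± 12.9 TPM, against 4.03 ± 0.0954 and 18.9 ± 1.04 in wild type. The auxin biosynthesis gene YUC8 (AT4G28720) was at 13.5 ± 1.32 against 2.95 ± 0.364 TPM at 22 °C and 27.7 ± 3.92 against 6.69 ± 0.533 TPM at 29 °C. Growth-related IAA19 (AT3G15540) was at 74.3 ± 17.2 against 4.23 ± 0.996 and 109 ± 3.16 against 24.04 ± 2.89 TPM.

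Evening complex targets rose in 8 of 8 members at each of these temperatures (8 and 8 adjusted over the list alone; medians 2.22 and 1.80, adjusted p = 4.3e-17 and 9.48e-11), and PIF and auxin growth genes in 30 and 29 of 33 with 0 and 1 lower (adjusted over the list alone, 30 and 30 rose and 0 and 2 fell; medians 1.61 and 1.18, adjusted p = 2.52e-30 and 1.99e-16). Evening clock genes rose in 10 and 10 of 11 (10 and 10 adjusted over the list alone; medians 1.22 and 1.61, adjusted p = 1.07e-12 and 3.7e-12). Photosynthesis genes were mixed at 22 °C, with 12 higher and 7 lower (13 and 7 adjusted over the list alone; adjusted p = 0.138), and fell at 29 °C in 17 of 24 with 4 higher (17 and 4 adjusted over the list alone; median -0.61, adjusted p = 1.81e-12, and adjusted p = 0.0588 with an estimated correlation). RBCS1B fell there by 2.80 and GUN4, an activator of chlorophyll synthesis, by 1.95. Root markers fell in 6 of 17 members at 22 °C and in 4 of 17 at 29 °C (6 and 4 adjusted over the list alone; medians -0.54 and -0.50, adjusted p = 0.0375 and 0.00387, and adjusted p = 0.593 and 0.433 with an estimated correlation). At 22 °C the call ended without S364P replicate 2 (adjusted p = 0.117) or wild-type replicate 1 (adjusted p = 0.1). The iron transporter gene IRT1, a root epidermis marker, fell by 3.37 ± 0.584 and 2.96 ± 0.584. Salicylic acid defence genes did not pass as a list at either temperature (adjusted p = 0.0748 and 0.584), though PAD4 fell by 0.82 and 1.15 ± 0.104. The counts were 3699 higher and 4249 lower at 22 °C and 5252 higher and 2935 lower at 29 °C, with 978 and 925 that differed by at least 1 log2. The share of higher calls at 22 °C was 46.5%, against 48.3% with median-of-ratios scaling and 53.2% with quantile normalization; 3262 of 6307 calls were higher without S364P replicate 2 and 3506 of 6718 without wild-type replicate 1. The share at 29 °C was 64.2%, against 51.4% with median-of-ratios scaling and 51.8% with quantile normalization. At 22 °C the falling terms were led by response to toxic substance (44 of 66 genes against 13.5 expected, adjusted p = 5.53e-13), glucosinolate biosynthesis (25 of 29 against 5.92, adjusted p = 2.81e-11) and amino acid biosynthesis (70 of 149 against 30.4, adjusted p = 1.01e-10). At 29 °C photosynthesis led, with 97 of 163 genes lower against 22.9 expected (adjusted p = 1.48e-38).

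**Figure D2:**
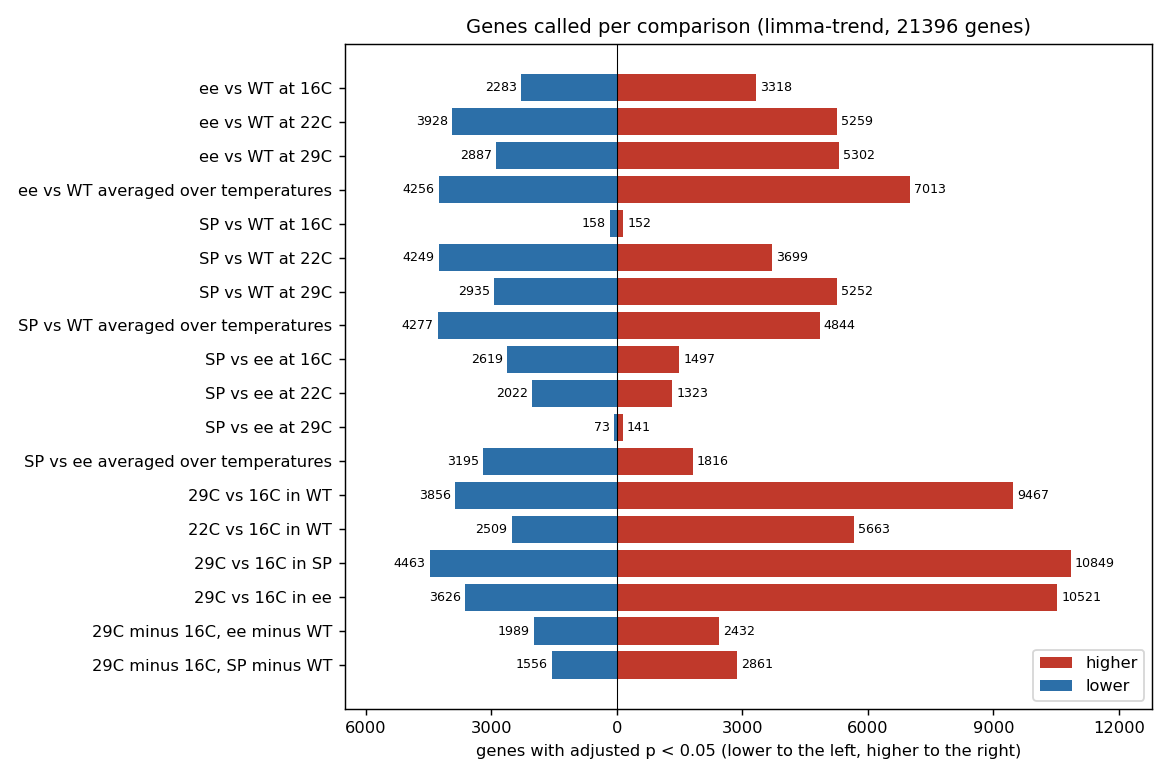
Number of genes with a limma adjusted p below 0.05 in each of the 18 comparisons, with genes higher to the right of 0 and genes lower to the left, out of 21396 tested, where WT is wild type, SP the S364P line and ee the insertion line. The S364P line differed from wild type in 310 genes at 16 °C and from the insertion line in 214 genes at 29 °C.

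Effects of both alleles were then set side by side across the 21396 genes, which are not independent replicates. At 16 °C 99 genes were higher in both lines and 143 lower in both, 5 went opposite ways, and 78.1% of the genes called in the S364P line were called in the same direction in the insertion line. At 22 °C 3245 were higher and 2702 lower in both, and at 29 °C 4044 and 2272, with 37 and 8 opposite. Independent lists of these sizes would share 40.5 genes in direction at 16 °C, 1689.3 at 22 °C and 1697.5 at 29 °C, against 242, 5947 and 6316 shared. The correlation of the log2 differences was 0.482 at 16 °C, 0.788 at 22 °C and 0.777 at 29 °C. Because both effects use the same wild-type libraries, unchanged groups simulated against shared controls gave 0.503, 0.502 and 0.498, and 0 genes called in both. The covariance was 0.0593, 0.24 and 0.198 against simulated 0.0261, 0.026 and 0.026, leaving 0.0332, 0.214 and 0.172. The last values have the simulated part of the shared controls taken off. The 3 wild-type libraries of a temperature do not give 2 parts of at least 2, so they were not split there, and part of the excess in shared genes may come from shared controls. For effects averaged over temperatures, with r = 0.796 and a covariance of 0.122 (simulated r = 0.493, covariance 0.00851), the 9 wild-type libraries were split into 4 and 5, and r was 0.736 and 0.663 for the 2 ways of assigning the parts. The slope of the S364P effect on the insertion effect, corrected for noise, was 0.212 at 16 °C, 0.727 at 22 °C and 0.887 at 29 °C; leaving out 1 library at a time kept it within 0.187 to 0.219, 0.688 to 0.749 and 0.844 to 0.93.

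**Figure D3:**
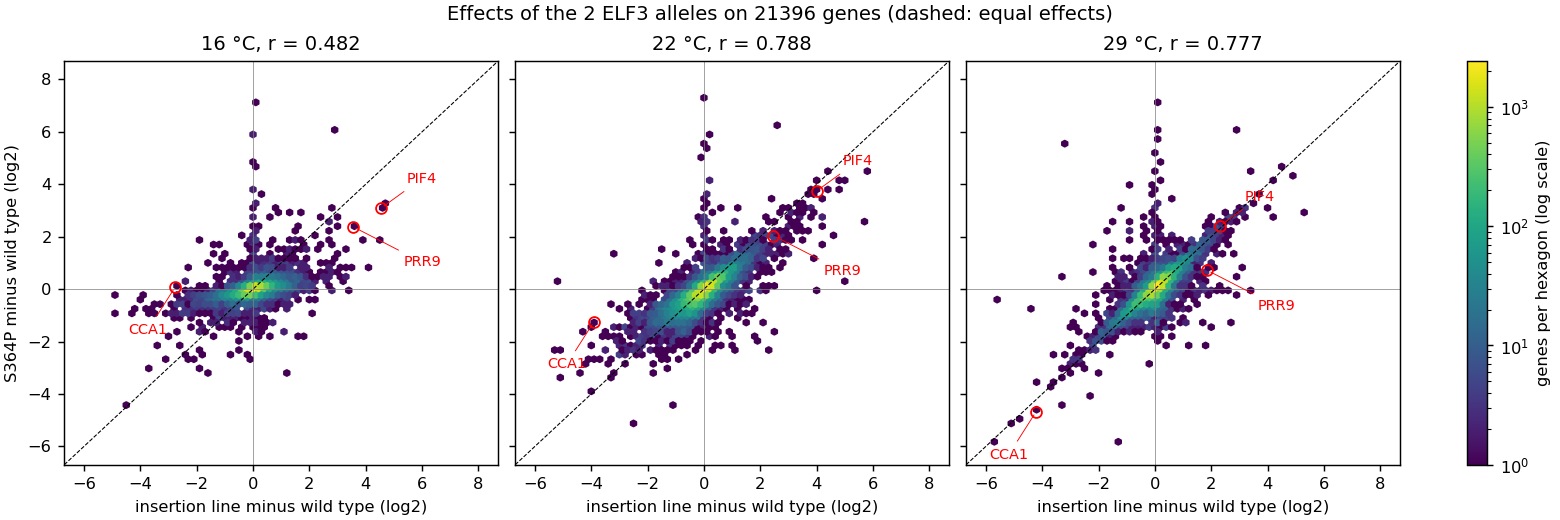
Log2 difference from wild type in the S364P line (vertical axis) against that in the insertion line (horizontal axis) for 21396 genes at 16, 22 and 29 °C, with hexagons coloured by the number of genes and a dashed line where both are equal. The noise-corrected slope was 0.212 at 16 °C and 0.887 at 29 °C.

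Compared directly with the insertion line at 16 °C, the S364P line had higher LHY and CCA1 and lower growth genes. LHY was higher by 3.63 ± 0.112 and CCA1 by 2.84 ± 0.098. IAA29 was lower by -3.18 ± 0.121, IAA19 by -2.59 ± 0.177 and GI by -2.59 ± 0.12. PIF4, which lay between wild type and the insertion line, was lower by -1.46 ± 0.088, and PIF5 was the growth gene that was higher, by 0.44 ± 0.065. The morning clock genes went both ways, 6 of 13 higher and 3 lower (6 and 4 adjusted over the list alone; median 0.053, mean 0.568, adjusted p = 0.00748, and adjusted p = 0.165 with an estimated correlation). PIF and auxin growth genes were lower in 27 of 33 members and higher in 1 (31 and 1 adjusted over the list alone; median -1.09, adjusted p = 3.6e-24). Flavonoid and anthocyanin genes were higher in 14 of 16 (15 adjusted over the list alone; median 1.31, adjusted p = 6.18e-21); both held with an estimated correlation. Rapid touch and wound genes were lower in 6 of 10 (9 adjusted over the list alone; median -0.73, adjusted p = 6.61e-05, and adjusted p = 0.112 with an estimated correlation). There were 1497 genes higher and 2619 lower, 484 of them by at least 1 log2 (254 higher). The share of higher genes, 36.4%, was 52.9% with median-of-ratios scaling and 50.7% with quantile normalization.

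At 22 °C, photosynthesis genes were higher in the S364P line than in the insertion line in 19 of 24 members (21 adjusted over the list alone; median 0.44, adjusted p = 4.88e-28, holding at adjusted p = 0.00748 with an estimated correlation), with LHCB2.1 at 1721 ± 160 against 439 ± 24.9 TPM. Morning clock genes were higher in 9 of 13 and lower in 1 (9 and 1 adjusted over the list alone; median 0.41, adjusted p = 2.45e-13), led by LHY (2.92) and CCA1 (2.66). Evening clock genes were lower in 10 of 11 (10 adjusted over the list alone; median -0.87, adjusted p = 2.91e-12). Cold response genes were lower in 10 of 17 (10 adjusted over the list alone; median -0.73, adjusted p = 2.71e-10). PIF and auxin growth genes did not pass (2 higher, 8 lower; 2 and 9 adjusted over the list alone; adjusted p = 0.4). IAA19 and IAA29 differed by 0.10 and 0.15 without passing, while XTR7 was lower by -2.86 ± 0.218. Counts were 1323 higher and 2022 lower, 224 of them by at least 1 log2 (140 higher). When the fit held only these 6 libraries, 592 were higher and 588 lower, 1180 in all. The share of higher genes, 39.6%, was 56.0% with median-of-ratios scaling and 58.6% with quantile normalization.

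At 29 °C few genes separated the ELF3 lines. Several core genes did not pass: LUX was at 114.5 ± 7.14 and 111 ± 6.39, PIF4 at 105 ± 12.9 and 97.3 ± 9.48, and IAA29 at 74.9 ± 5.35 and 77.9 ± 11.1 TPM in the S364P and insertion lines. ELF3 was higher in the S364P line by 0.80 ± 0.078 (adjusted p = 5.40e-07) and PRR9 lower by -1.15 ± 0.089 (adjusted p = 1.04e-08). CCA1 was lower by -0.46 ± 0.098 (adjusted p = 0.0225). The largest differences were transcripts near 0 in a single line. MSTRG.15205 was at 139 ± 10.1 TPM in the S364P line and listed at 0 in the insertion line. MRD1 (AT1G53480) was at 37.9 ± 5.09 TPM in the S364P line and listed at 0 in all 3 insertion-line libraries. Of the 17 lists, 4 passed with the preset correlation and none with an estimated one. Root markers were lower in 1 of 17 members (7 adjusted over the list alone; median -0.65, adjusted p = 9.81e-06, and adjusted p = 0.418 with an estimated correlation). Morning clock genes were lower in 4 of 13 (4 adjusted over the list alone; median -0.11, adjusted p = 0.00434, and adjusted p = 0.4 with an estimated correlation). Photosynthesis genes were higher in 1 of 24 (1 adjusted over the list alone; median 0.07, adjusted p = 0.0106, and adjusted p = 0.685 with an estimated correlation). Flowering promoters were higher in 0 of 8 (1 adjusted over the list alone; median 0.19, adjusted p = 0.0202, and adjusted p = 0.4 with an estimated correlation). The morning clock call ended without S364P replicate 1 (adjusted p = 0.129). The photosynthesis and flowering promoter calls ended without insertion-line replicate 1 (adjusted p = 0.613 and 0.0836) or S364P replicate 3 (adjusted p = 0.391 and 0.183), and the flowering promoter call also with a filter of 5 TPM (adjusted p = 0.122). Counts were 141 higher and 73 lower, 71 of them by at least 1 log2, with 53 in a fit of these 6 libraries. The balance turned without S364P replicate 1, the library with the higher root score, when 1404 genes passed and 516 of them were higher. It also turned with the root score as a covariate, chosen after seeing the data, with 395 higher and 836 lower. Without S364P replicate 2 or 3, 92 and 94 genes passed, and without insertion-line replicate 3, 84.

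**Figure D4:**
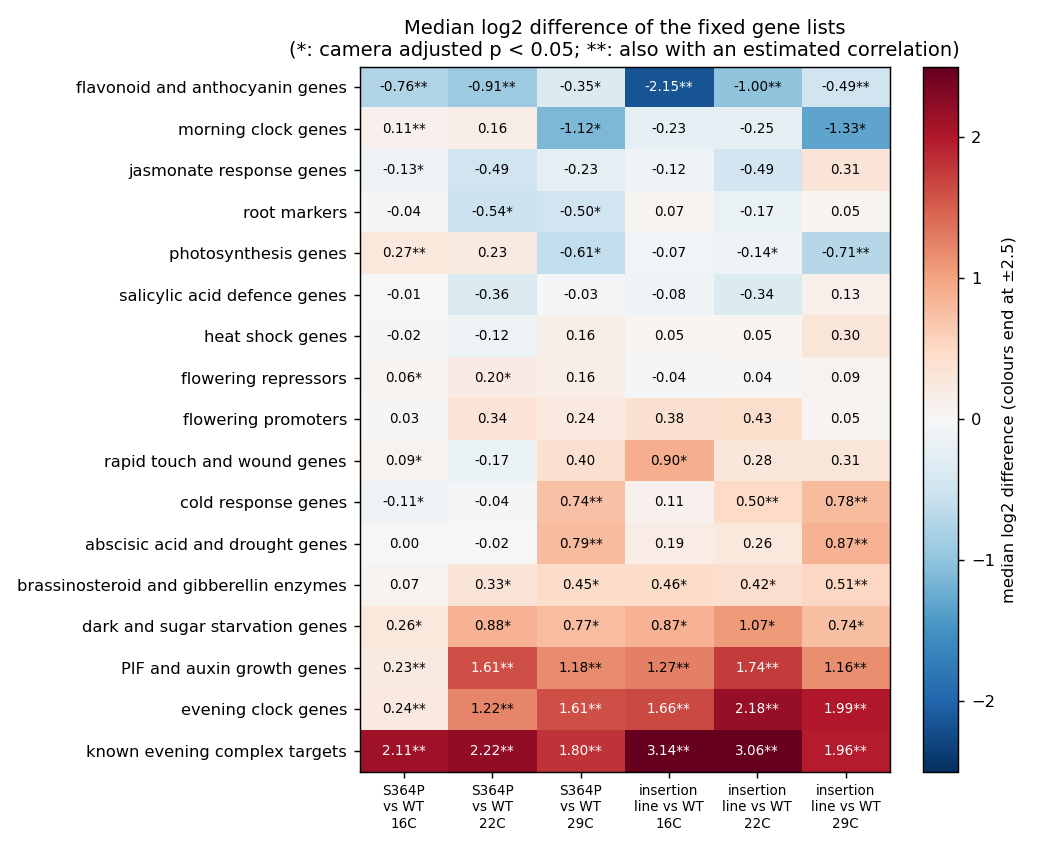
Median log2 difference of each fixed gene list (vertical axis) in the S364P and insertion lines against wild type at 16, 22 and 29 °C (horizontal axis), coloured from blue for lower to red for higher. One star marks a camera adjusted p below 0.05 with the preset correlation and a pair of stars one that also holds with an estimated correlation. Evening complex targets had medians from 1.80 to 3.14.

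Within wild type 29 °C was compared with 16 °C, with the reservation on time of day given above. Heat shock genes rose: HSP70 went from 2.15 ± 0.234 to 52.5 ± 5.93 TPM and HSP90.1 from 1.35 ± 0.127 to 38.2 ± 0.105. Cold markers fell, with KIN1 going from 102 ± 5.77 to 2.90 ± 0.660 TPM. The light-stress proteins ELIP1 and ELIP2 fell from 103 ± 9.03 to 1.21 ± 0.282 and from 168 ± 12.9 to 2.53 ± 0.0777 TPM. PIF4 rose from 0.787 ± 0.0321 to 18.9 ± 1.04 TPM and DIN1, a dark-inducible senescence gene, from 16.4 ± 6.90 to 557 ± 133. CCA1 fell by 0.97 ± 0.098, while LHY differed by -0.20 (adjusted p = 0.12) and PRR9 by -0.06 (adjusted p = 0.612).

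Heat shock genes rose in 22 of 24 members (22 adjusted over the list alone; median 1.51, adjusted p = 6.61e-06, and adjusted p = 0.112 with an estimated correlation). Cold response genes fell in 11 of 17 with 2 higher (11 and 2 adjusted over the list alone; median -1.35, adjusted p = 7.17e-07), and flavonoid genes fell in 14 of 16 (14 adjusted over the list alone; median -2.15, adjusted p = 1.97e-14); the last pair held with an estimated correlation. PIF and auxin growth genes rose in 29 of 33 and fell in 1 (30 and 1 adjusted over the list alone; median 1.52, adjusted p = 1.22e-08, and adjusted p = 0.0979 with an estimated correlation). Photosynthesis genes fell in 20 of 24 (20 adjusted over the list alone; median -0.62, adjusted p = 2.77e-13, and adjusted p = 0.0979 with an estimated correlation). Flowering repressors fell in 8 of 18 and rose in 3 (8 and 3 adjusted over the list alone; median -0.10, adjusted p = 0.0083, and adjusted p = 0.0979 with an estimated correlation), while flowering promoters did not pass (adjusted p = 0.499). SPL3 rose by 3.40 ± 0.151 and FT, the mobile flowering signal, fell by 0.95 ± 0.131 from 0.940 ± 0.147 TPM to a listed 0. Between 22 and 16 °C, cold response genes fell in 14 of 17 with 1 higher (15 and 1 adjusted over the list alone; median -1.09, adjusted p = 2.52e-13). Heat shock genes rose in 10 of 24 without passing as a list (10 adjusted over the list alone; adjusted p = 0.0797). Jasmonate response genes did not pass at 29 or at 22 °C (adjusted p = 0.805 and 0.928). At 29 °C 9467 genes were higher and 3856 lower than at 16 °C, and at 22 °C 5663 and 2509; 2705 and 622 differed by at least 1 log2. The median over all genes was 0.21 at 29 °C, and median-of-ratios scaling moved it to 0.006. That scaling changed the share of higher calls from 71.1% to 50.1% at 29 °C and from 69.3% to 50.7% at 22 °C; quantile normalization gave 48.7% and 49.8%. Photosynthesis was the leading falling term at 29 °C (98 of 163 genes against 30.1 expected, adjusted p = 3.74e-29), followed by chloroplast organization, rRNA processing (78 of 179 against 33.1, adjusted p = 2.69e-12) and ribosome biogenesis, and ubiquitin-dependent protein catabolism led the rising terms (144 of 220 against 98.7, adjusted p = 4.54e-07).

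In the S364P line, CCA1 changed by -5.73 ± 0.098 and LHY by -5.56 ± 0.112 from 16 to 29 °C. ST2A, a jasmonate sulfotransferase gene, rose by 7.13 ± 0.155 from 1.62 ± 0.275 to 365 ± 10.1 TPM and XTR7 by 6.32 ± 0.218 to 1100.0 ± 143. In the insertion line XTR7 rose by 6.13 ± 0.218 and FLP1 by 5.62 ± 0.178, from 0.773 ± 0.344 to 85.5 ± 8.11 TPM, and CCA1, already low at 16 °C, fell by 2.43 ± 0.098. Photosynthesis genes fell in 24 of 24 members in the S364P line and 23 of 24 in the insertion line (24 and 23 adjusted over the list alone; medians -1.62 and -1.49, adjusted p = 9.01e-20 and 8.94e-23, holding with an estimated correlation). Heat shock genes rose in 20 of 24 in both (20 and 20 adjusted over the list alone; medians 1.80 and 1.92, adjusted p = 1.2e-04 and 2.07e-05, and adjusted p = 0.187 and 0.12 with an estimated correlation). Counts were 10849 higher and 4463 lower in the S364P line, and 10521 higher and 3626 lower in the insertion line; 4875 and 3151 differed by at least 1 log2. The shares of higher calls, 70.9% and 74.4%, were 50.9% and 50.3% with median-of-ratios scaling and 50.5% and 52.3% with quantile normalization.

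Whether the change from 16 to 29 °C differed by genotype was tested as an interaction. In the S364P line the CCA1 and LHY responses were more negative than in wild type, by -4.76 ± 0.139 and -5.36 ± 0.159. The COR413IM1 and XTR7 responses were more positive by 4.27 ± 0.273 and 4.38 ± 0.308. Its interaction was negative for photosynthesis genes in 20 of 24 members (21 adjusted over the list alone; median -0.80, adjusted p = 8.97e-29) and positive for evening clock genes in 10 of 11 (10 adjusted over the list alone; median 1.3, adjusted p = 9.82e-13), which held with an estimated correlation. In the insertion line the interaction of evening complex targets was negative in 7 of 8 members (7 adjusted over the list alone; median -1.26, adjusted p = 4.41e-11), with PIF4 at -2.25 ± 0.125 and PRR7 at -1.89 ± 0.172. The interaction was positive for flavonoid genes in 14 of 16 (14 up and 1 down adjusted over the list alone; median 1.24, adjusted p = 4.06e-13) and negative for photosynthesis genes in 17 of 24 (17 adjusted over the list alone; median -0.81, adjusted p = 3.16e-20); these 3 held with an estimated correlation. The PIF4 interaction of the S364P line depended on the scale: it was -0.68 with a pseudocount of 1 and 0.47 with a pseudocount of 5 (adjusted p = 0.00465). Among evening complex targets in the insertion line, the calls of GI (adjusted p = 0.531) and LUX (adjusted p = 0.352) ended with a pseudocount of 5. The lists were not tested with that pseudocount. The counts were 2861 higher and 1556 lower for the S364P line and 2432 and 1989 for the insertion line, with 734 and 627 of at least 1 log2. The share of higher calls of the S364P interaction, 64.8%, was 48.3% with median-of-ratios scaling and 49.2% with quantile normalization, and that of the insertion line, 55.0%, was 44.4% with median-of-ratios scaling and 49.1% with quantile normalization. Without insertion-line replicate 2 at 16 °C, 1791 of 3613 calls of that line were higher.

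Averaged over temperatures, the insertion line differed from wild type in 7013 genes higher and 4256 lower, the S364P line from wild type in 4844 and 4277, and the S364P line from the insertion line in 1816 and 3195; 802 (400 higher), 326 and 126 (91 higher) of these differed by at least 1 log2. PIF4 was higher by 3.62 ± 0.051 in the insertion line and by 3.09 ± 0.051 in the S364P line. Brassinosteroid and gibberellin enzyme genes rose in 10 of 14 members and fell in 1 in both lines (10 and 1 adjusted over the list alone; medians 0.46 and 0.25, adjusted p = 0.00151 and 0.00225, and adjusted p = 0.11 and 0.115 with an estimated correlation). Among flowering genes CO was higher by 0.62 ± 0.05 and 0.35 ± 0.05, and SOC1 by 0.56 ± 0.068 and 0.33 ± 0.068, but neither flowering list passed in either line (promoters adjusted p = 0.181 and 0.0891, repressors adjusted p = 0.781 and 0.142). FT was below 1 TPM on average in every group but the insertion line at 16 °C, where it was at 2.04 ± 0.390 against 0.940 ± 0.147 TPM in wild type. That difference of 0.64 passed with a pseudocount of 1 (adjusted p = 7.28e-04) and not with 0.1 (adjusted p = 0.177). The share of higher calls in the insertion line, 62.2%, was 50.7% with median-of-ratios scaling. That in the S364P line, 53.1%, was 49.3%, and without its replicate 1 at 29 °C 4664 of 9530 calls were higher. The share between the ELF3 lines, 36.2%, was 56.1%, or 52.4% with quantile normalization.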

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

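The tests of time of day, mislabelled libraries and precision, and the splits with additive effects removed, were chosen after the results were seen; the other splits were planned.

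The response to 29 °C against 16 °C differed between genotypes by the interaction test, which put the results of this part here. It called 4421 genes for the insertion line and 4417 for the S364P line, each against wild type. Among lists of the insertion line, morning clock genes had a median of -1.171, evening complex targets -1.257, photosynthesis genes -0.81 and touch and wound genes -0.664. Cold response genes stood at 0.602, flavonoid genes at 1.24 and abscisic acid genes at 0.75. With an estimated correlation the cold call ended (adjusted p = 0.0662), as did the touch call (adjusted p = 0.275). Genes of the insertion line were CCA1 at -1.456, LHY at -1.62, PRR7 at -1.886, PRR9 at -1.682, GI at -0.855, LUX at -0.582 and PIF4 at -2.245. YUC8 was at 0.874, IAA19 at -0.888, IAA29 at -1.799, FT at -0.582 and SOC1 at -0.669. With a pseudocount of 5 the calls of GI (adjusted p = 0.531), LUX (adjusted p = 0.352) and IAA19 (adjusted p = 0.359) ended. The FT call ended with a pseudocount of 0.1 (adjusted p = 0.626). It also ended without insertion-line replicate 1 (adjusted p = 0.0702) or 3 (adjusted p = 0.064) at 16 °C, or replicate 1 (adjusted p = 0.0591) or 3 (adjusted p = 0.0642) at 29 °C. The same held without wild-type replicate 2 at 16 °C (adjusted p = 0.0795) or replicate 3 at 29 °C (adjusted p = 0.0508).

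Among lists of the S364P line, morning clock genes had a median of -1.617, evening clock genes 1.3, PIF and auxin growth genes 0.76, brassinosteroid and gibberellin enzymes 0.338 and cold response genes 1.049. Photosynthesis genes stood at -0.798, abscisic acid genes at 0.732, dark and sugar starvation genes at 0.54 and root markers at -0.591. With an estimated correlation the growth call ended (adjusted p = 0.083), as did the calls of the enzymes (adjusted p = 0.141), the dark genes (adjusted p = 0.462) and the root markers (adjusted p = 0.502). The dark and sugar call also ended without S364P replicate 3 at 29 °C (adjusted p = 0.126) or wild-type replicate 2 at 29 °C (adjusted p = 0.0945), and with a filter of 5 TPM (adjusted p = 0.0507). Genes of the S364P line were ELF3 at 0.605, CCA1 at -4.757, LHY at -5.355, TOC1 at 1.375, PRR5 at 1.25, PRR9 at -1.668, GI at 1.499 and ELF4 at 1.367. With a pseudocount of 0.1 the GI value turned to -0.014 and its call ended (adjusted p = 0.983). LUX was at 1.3, PIF4 at -0.681 (0.466 with a pseudocount of 5), PIF5 at -0.472, YUC8 at 1.686, IAA19 at 1.59, IAA29 at 1.331 and CO at 0.752.

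The S364P line lay near wild type at 16 °C and near the insertion line at 29 °C. The 214 genes called between the ELF3 lines at 29 °C depended on single libraries, with 84 to 1404 called when 1 was left out. The 1404 were called without S364P replicate 1. That library correlated with the insertion-line libraries at 29 °C at r = 0.975 to 0.980, and with S364P replicates 2 and 3 at 0.974 and 0.973. A lower precision at 16 °C is argued against by the noise-corrected slope, 0.212 at 16 °C and 0.887 at 29 °C, with ranges that do not meet when 1 library is left out. Insertion-line libraries under S364P labels at 29 °C are argued against by 44 of 50 genes, higher in the S364P line at 16 and 22 °C, whose 3 libraries at 29 °C all lay above the 6 others. The protocol read literally sets 16 °C in the afternoon and 29 °C at dawn, ZT 24. CCA1 in wild type, at -0.975 for 29 against 16 °C, argues against this pairing. A dawn sample would be far higher than one from the afternoon. The difference alone does not show which of the times is wrong. Wild-type CCA1 was at 258 to 282 TPM at 16 °C, 221 to 228 at 22 °C and 122 to 148 at 29 °C. LHY was at 305 to 321, 447 to 471 and 249 to 298 TPM. No temperature was far above both others in both genes, as a dawn sample would be. For these genes, this argues against the other assignments of the protocol times to temperatures. A candidate explanation that stays open is that the changed protein may lose activity with warmth. No protein was measured, and sampling times outside the protocol were not tested. With 1 listed time per temperature, a change in level cannot be told from a change in daily timing.

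For each comparison of 3 against 3 libraries, the 10 possible splits are too few for a share under 0.05. The real split called most genes, 1 of 10, in all of these but one. For the insertion line against wild type the real values were 5601, 9187 and 8189 at 16, 22 and 29 °C, with 3, 2 and 1 as the highest others. For the S364P line against wild type they were 310, 7948 and 8187, with 1, 0 and 69. For the S364P line against the insertion line they were 4116, 3345 and 214, with 1, 649 and 1063. At 29 °C 2 of 10 splits called as many, and the split with 1063 genes set S364P replicate 1 with insertion-line replicates 1 and 3, which points to a structure among these samples. For 29 against 16 °C the values were 13323, 15312 and 14147 in the wild type, the S364P line and the insertion line, with 2, 0 and 2 as the highest others, and for 22 against 16 °C in wild type 8172 with 1.

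For the averaged comparisons 1 of 100 splits, the real one, called as many genes, which argues against a chance assignment of these libraries. Splits cannot tell genotype from any other difference between groups, and replicates may be technical. The insertion line against wild type called 11269 with 4700 as the highest other, the S364P line against wild type 9121 with 4346, and the S364P line against the insertion line 5011 with 2275. For the interactions 5 of 100 splits called as many for the insertion line (highest other 5738) and 12 of 100 for the S364P line (highest other 5310), so chance was not excluded. The other splits with as many genes kept the libraries of 1 temperature whole and so held main effects. With additive effects removed, 1 of 100 splits, the real one, called as many in each line, with 941 and 1173 as the highest others. This argues against a chance assignment within the same limit, in a version chosen after the planned result.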

How the results depend on the processing

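The root score as a covariate and the filter on wild-type and insertion-line libraries were chosen after seeing the data; the other alternatives were planned. Depth limits nothing that can be stated here, since TPM keeps none.

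A minimum difference of 1 log2 lowered every count, as its construction requires. At 16, 22 and 29 °C it left 717, 1338 and 939 for the insertion line against wild type, 62, 978 and 925 for the S364P line against wild type, and 484, 224 and 71 between the ELF3 lines. The averaged comparisons kept 802, 326 and 126. Temperature comparisons kept 2705 and 622 in wild type at 29 and 22 °C, 4875 in the S364P line and 3151 in the insertion line, and the interactions 734 for the S364P line and 627 for the insertion line.

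A fit of the groups compared alone left 1180 genes between the ELF3 lines at 22 °C, 1141 of them shared with the count of 3345, and 53 at 29 °C, with 50 shared; it has fewer residual degrees of freedom. The root score as a covariate raised the count at 29 °C from 214 to 1231, with all 214 shared. With a pseudocount of 0.1 the correlation of both alleles' effects was 0.7241 at 22 °C, 0.6747 at 29 °C and 0.7068 averaged. The cause was not tested. The replicate number as a block, which had no value where the insertion line at 16 °C takes part, moved no count by over 1.5 times: the S364P line against wild type at 16 °C gave 334.

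Leaving out 1 library gave 191 to 256 genes for the S364P line against wild type at 16 °C and 84 to 1404 between the ELF3 lines at 29 °C.

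Directions turned in these cases, and the cause was not tested. AOS at 29 against 16 °C in wild type was -0.006 with quantile normalization. BCAT2 in the interaction of the insertion line was -0.015 and GI in that of the S364P line -0.014 with a pseudocount of 0.1. ELF3 at 29 against 16 °C in the insertion line was -0.028 with median-of-ratios scaling and -0.019 with quantile normalization, and FLC in the S364P line was -0.028 with quantile normalization. PIF4 in the interaction of the S364P line was 0.466 with a pseudocount of 5. ELF3 in the insertion line against wild type at 29 °C, never called, ranged from -0.06 without insertion-line replicate 1 to 0.007 without replicate 2.

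Of 159 list calls, 79 held with an estimated correlation and 80 ended. A filter of 5 TPM ended 10 of them, a pseudocount of 0.1 ended 3 and quantile normalization 1; with the replicate block 3 ended and 100 held. Of 1237 single-gene calls, those that ended, turned ones included, numbered 33 with median-of-ratios scaling, 36 with quantile normalization, 36 and 20 with pseudocounts of 0.1 and 5, 71 in a fit of the groups compared alone, 23 without the filter and 0 with organelle-encoded genes removed. The replicate block could be fitted for 798 of them and ended 6, and 1147 passed a filter of 5 TPM, which ended 2. Leaving out 1 library ended 391 of 10926 single-gene calls, each call counted once per library left out. Of the list calls counted in this way, 31 ended and 1367 held.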

Other observations

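The tests in this part were chosen after the results were seen.

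Transcripts mostly silent in the other genotypes were higher in the S364P line at every temperature. In all 6 comparisons with wild type and the insertion line, 44 genes were higher and 1 was lower, AT2G06995, chosen after its values were seen. They held 17 genes of the DNA integration term, of which 15 passed the expression filter only through S364P libraries, so no enrichment of the term is claimed. Assembled loci numbered 23, and the 44 genes made up 28.9% of the genes higher than wild type at 16 °C and 31.2% of those higher than the insertion line at 29 °C. Of them, 37 were below 1 TPM on average in the other genotypes. Counted in the same way against both other genotypes, the insertion line had 6 genes higher and 37 lower. Wild type had 99 higher and 66 lower, which can hold effects shared by both ELF3 lines, so its counts are no baseline. The insertion line thus also had genes set apart at every temperature, mostly lower, while those of the S364P line were mostly higher.

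Genomic DNA in the S364P libraries is argued against, since 0.39% of 9324 silent genes reached 1 TPM in the S364P line, 36 genes against 25 for the insertion line and 21 for wild type. Reads of 1 element counted at all members of the DNA integration term are argued against by their responses to 29 °C, from -2.37 to 1.49. This range cannot tell how many members were active, since reads of a few elements may still be counted at related copies. Another accession as background would also lower genes, and 1 was lower. A general loss of DNA methylation is argued against by ROS1, a gene that falls when methylation is lost, at 0.093 averaged over temperatures. ROS1 is 1 gene, and a loss limited to the silent loci themselves was not tested. A candidate explanation that stays open is that a set of mobile elements may have become active in the history of this line, apart from the ELF3 change; the design has 1 S364P line, so both cannot be separated.

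IRT1 was lower in the insertion line than in wild type by -3.312 at 22 °C and -2.462 at 29 °C. A smaller share of root in the samples is argued against, since 16 other root markers had a median of -0.16 at 22 °C, from -0.8 to 1.03, and of 0.05 at 29 °C, from -0.08 to 0.61. A single library is argued against by -2.842 at 22 °C and -1.903 at 29 °C, the IRT1 values nearest to 0 when 1 library was left out. That the iron response may follow the clock in these seedlings stays open and was not tested.

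MRD1 was listed at 0 TPM in the insertion line at 16 and 29 °C and was at 28.9 TPM in wild type at 16 °C.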
